A study of Macaca fascicularis with 16 samples.

How the data were processed

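Total RNA from mammary tissue of 16 ovariectomized postmenopausal cynomolgus macaques was extracted with Tri-reagent and Qiagen RNeasy columns, labelled with biotin and hybridized to Affymetrix rhesus macaque arrays, 1 array per animal, per the labels. The 4 groups of 4 animals were control (no treatment), conjugated equine estrogens (CEE, 0.042 mg/kg), CEE with medroxyprogesterone acetate (CEE+MPA, 0.042 and 0.167 mg/kg) and tibolone (0.2 mg/kg). Replicate numbers were assigned in the order of the deposited arrays, and no paired analysis was possible because each animal belonged to 1 group.

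The deposited values were linear intensity (signal) for each probe set, scaled by the authors so that every array had the same mean after trimming 2% of the values at each end (250.02 in 15 arrays and 250.01 in 1). They were neither log transformed nor quantile normalized. The submitters' processing notes named GCOS and Affymetrix Expression Console, and the algorithm and versions are not given in the sources used here.

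Of 52865 probe sets, 99 were Affymetrix controls and were left out of the tests. A symbol was assigned to 25330 probe sets by the annotation table, of which 361 carried several symbols and were not named as genes, and 27535 carried none. A probe set was tested if its signal exceeded 60.2, the median of the table, in at least 4 of the 16 arrays, which left 28716 probe sets. These held 10455 genes, each represented by its tested probe set with the highest mean of log2(signal + 16) over all arrays. Probes were designed for another macaque species, and 9560 of the tested symbols were found in the cynomolgus RefSeq gene table as a symbol or synonym.

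Signals were transformed as log2(signal + 16), so fold changes of genes with low signal are understated. One limma model with 4 group means was fitted over all 16 arrays, and 6 comparisons were tested with moderated statistics, adjusted by Benjamini and Hochberg within each comparison at 0.05. Errors of log2 fold changes are standard errors from that model, and errors of signals are standard deviations. Arrays carry no read depth, so their number limits the precision.

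Before the data were examined, 28 gene lists were fixed for hormone responses, cell types, growth factor pathways and stress, with 823 distinct members, of which 517 were tested. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists, and again with a correlation estimated for each list and with fry. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. List means per array, with each gene centred on its mean over the 16 arrays, were compared by exact two-sided permutation tests, adjusted over 90 tests.

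Genes were named by a rule fixed before the data were examined. In each comparison these were the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, or 5 each way for tibolone against CEE and against CEE+MPA. Where fewer than 3 passed in a direction, the 3 with the smallest p were named as well. The 4 members with the smallest p in each list past its threshold and a fixed panel of 14 genes were added. Other probe sets that are named were chosen after their values were seen, and are said to be so.

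Alternatives tried were quantile normalization, median centring, no filter, a stricter filter at the 75th percentile, offsets of 1 and 64, a trended prior, array weights, models of only the groups compared, 1 probe set per gene and a threshold of 0.10. Covariates tried were the 3 prime to 5 prime ratio of control transcripts and the luminal epithelial mean, and each array was left out in turn. A skeletal muscle covariate, the omission of 4 arrays with high skeletal muscle signal, 2 codings of the signals of the poly-A spike-in controls and 1 coding of the arrays by the 3 prime to 5 prime ratio of GAPDH were added after the data were seen. The pipeline was tested on simulated data with 100 changed probe sets at a log2 size of 1 and 100 at a size of 2. The simulated noise was independent between probe sets, without sets of arrays or differences in tissue. At a size of 2 between 92 and 97 of the 100 were recovered across the 6 comparisons, and at a size of 1 between 54 and 70. In the same simulations 6 to 14 unchanged probe sets were called. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.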

Results

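Expression was measured in mammary tissue of cynomolgus macaques that had received no treatment (control), CEE, CEE+MPA or tibolone, a synthetic steroid, in a study of hormone replacement therapy. Each group held 4 animals with 1 array each. The share of probe sets above a signal of 60.2 lay between 48.6% and 51.8% on the 16 arrays. Markers of skeletal muscle, which is not part of the mammary gland, stood out on 4 arrays: the list mean exceeded 1 on control replicate 1 (2.52), CEE+MPA replicate 1 (1.35), tibolone replicate 2 (2.41) and tibolone replicate 3 (1.51). All 4 CEE arrays had low skeletal muscle signal, with a mean of -0.94 ± 0.10 (SD, n = 4).

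The spike-in controls dap and thr, bacterial transcripts usually added before RNA labelling, divided the arrays into 2 sets that the labels do not name. A low set of 6 held 2 control, 2 CEE and 2 CEE+MPA arrays, with dap at 7.13 to 7.44 on the log2 scale. The high set of 10 held the other 2 arrays of each of these groups and all 4 tibolone arrays, with dap at 7.70 to 8.52. Between the sets 693 probe sets differed in a limma model with group. The second principal component, with 10.3% of the variance, lay at -32.2 to -15.5 on the low set and at 1.48 to 30.7 on the high set. The log2 3 prime to 5 prime ratio of GAPDH was 0.002 to 0.247 in the low set. In the high set it was 0.663 to 0.778 on control, CEE and CEE+MPA arrays and 0.105 to 0.873 on tibolone arrays. Counts with the sets as a block, and counts within a set, are given with each comparison. Those within a set came from 1 limma model over all 16 arrays, with a mean for each group in each set. The difference was taken between arrays of that set, and its error was pooled over all arrays. Lists with the sets as a block or within a set were tested with camera at the preset correlation only. Such p values treat the genes of a list as nearly independent and do not measure the spread between animals. Whether an effect differed between the sets was not tested. Tibolone can be compared within the high set only, and there not at equal spike-in levels. With 3 sets, all 4 tibolone arrays lay in a middle set (dap 7.70 to 8.06) with 1 control, 1 CEE and 0 CEE+MPA arrays, while the CEE+MPA arrays of the high set had dap at 8.46 and 8.52.

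**Figure D1:**
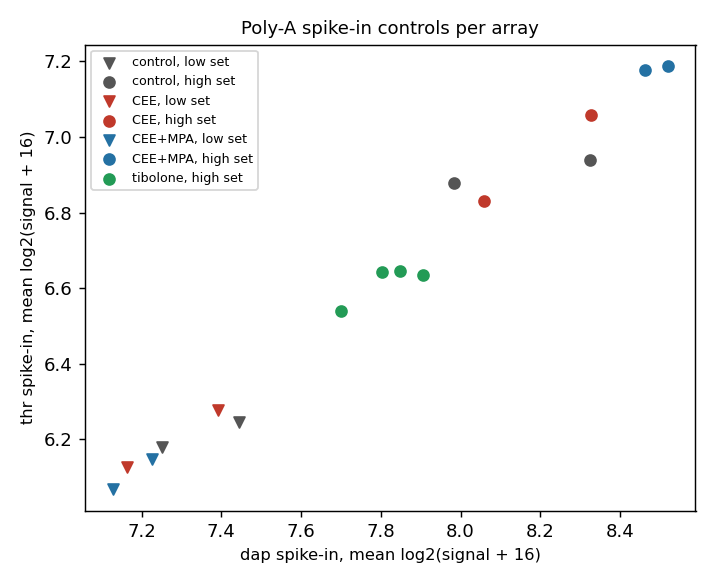
Mean log2(signal + 16) of the poly-A spike-in controls dap (horizontal axis) and thr (vertical axis) on each of the 16 arrays, 1 point per array, with triangles for the low set and circles for the high set. The low set of 6 lies at dap values of 7.13 to 7.44 and holds no tibolone array.

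CEE was compared with no treatment, which addresses the response to estrogen alone. GREB1, an estrogen receptor target, rose from a signal of 29.1 ± 8.95 in controls to 394 ± 118 with CEE (SD, n = 4 each), a log2 fold change of 3.15 ± 0.24 (limma, adjusted p = 2.2e-05). IGFBP1, which encodes a binding protein for insulin-like growth factors, rose from 57.8 ± 36.9 to 1019 ± 885, by 3.63 ± 0.43 (adjusted p = 0.00211). BCAS1, a gene first found amplified in breast cancer, rose by 1.35 ± 0.22 (adjusted p = 0.0346), and RBBP8, a DNA repair gene, by 1.33 ± 0.22 (adjusted p = 0.0346). FST, which encodes the activin-binding protein follistatin, changed by -1.06 ± 0.18 (adjusted p = 0.0384), and HTRA1, a secreted protease gene, by -0.998 ± 0.15 (adjusted p = 0.0161). GREB1 and IGFBP1 were higher, and FST and HTRA1 lower, on every CEE array than on every control array. FBLN1, the fibulin 1 gene of the extracellular matrix, had the smallest p among genes that were lower but did not pass, with signals of 1018 ± 224 against 2731 ± 846 and a log2 fold change of -1.38 ± 0.25 (adjusted p = 0.0504).

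In all, 12 probe sets were higher and 9 lower with CEE than control, 21 of 28716 tested, and 3575 had an unadjusted p under 0.05 where 1436 would by chance. The count was 33 with the spike-in sets as a block, and within each set of 2 against 2 arrays 2 passed, both higher. All 21 kept their direction in each set, which was partly built in because they were chosen on these arrays. Without a single array the count was 6 (CEE replicate 1), 8 (control replicate 2), 9 (control replicate 3), 10 (CEE replicate 2 or CEE replicate 4) or 12 (CEE replicate 3). It was 8 with a skeletal muscle covariate. GREB1 and IGFBP1 passed under every alternative. BCAS1, RBBP8 and FST missed the threshold when any CEE array or any of control replicates 1, 2 and 3 was left out (highest adjusted p 0.103, 0.150 and 0.153). HTRA1 missed it without control replicate 2, CEE replicate 1 or CEE replicate 4 (highest adjusted p over all alternatives 0.0804).

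Lists of stromal cell markers and the myeloid list lay lower with CEE than control, while the T and NK cell list (camera adjusted p = 0.270) and the B and plasma cell list (0.280) did not pass. The myeloid list fell (median log2 fold change -0.68 over 20 genes, camera adjusted p = 1.54e-06), as did fibroblast and matrix genes (-0.38 over 27, adjusted p = 4.14e-05), endothelial genes (-0.34 over 19, adjusted p = 7.44e-05) and smooth muscle genes (-0.40 over 15, adjusted p = 0.000265). Skeletal muscle genes (-1.14 over 17, adjusted p = 0.000473), adipocyte genes (-0.50 over 27, adjusted p = 0.000555), interferon response genes (-0.26 over 23, adjusted p = 0.000894) and immediate early and stress genes (-0.41 over 19, adjusted p = 0.0105) fell too. None of the 8 lists passed with an estimated correlation: adjusted p = 0.472 for myeloid, fibroblast and endothelial genes, 0.481 for smooth muscle and 0.665 for the other 4 with an estimated correlation. With fry none of the 8 passed (lowest adjusted p 0.131). No member of the 8 lists passed over all genes. Adjusted over the list alone, 7 myeloid genes fell, 1 interferon gene fell, and 5 fibroblast and matrix genes fell while 1 rose.

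Among myeloid genes, the macrophage marker CD68 had a signal of 320 ± 135 with CEE against 777 ± 160 in controls, and C1QB, a complement gene, 844 ± 282 against 1650 ± 302. MS4A7 stood at a log2 fold change of -0.82 ± 0.19 and CLEC7A by -0.67 ± 0.21. In the matrix list OGN stood at -1.45 ± 0.28, DPT by -1.47 ± 0.30 and COL3A1 by 0.63 ± 0.16. Endothelial members EMCN, RAMP2, TEK and ERG stood at -0.51, -0.52, -0.50 and -0.28, smooth muscle members SYNPO2, KCNMB1, CALD1 and PGM5 by -0.47, -0.52, -0.34 and -0.53, and adipocyte members RETN, CFD, GPAM and CAV1 by -0.80, -0.99, -0.88 and -0.35. Skeletal muscle genes had larger errors, with MYL1 at -2.95 ± 1.63, TNNT3 at -1.70 ± 0.68, ACTN2 at -1.23 ± 0.56 and ACTN3 at -1.13 ± 0.41. Interferon members SAMD9L, IRF7, CXCL9 and IFIH1 stood at -0.64, -0.75, -0.92 and -0.36, and the stress list's FOS, BTG2, CCN1 and MYC by -1.47, -0.57, -1.04 and 0.53. The estrogen response list did not pass (adjusted p = 0.356), with 2 members higher over all genes, and 5 higher and 4 lower adjusted over the list alone. Without control replicate 1 the skeletal muscle and stress lists missed the threshold (adjusted p = 0.199 and 0.288), as did the stress list without CEE replicate 2 (0.0532), the interferon list without control replicate 4 (0.133) and adipocyte genes without CEE replicate 4 (0.0527). With the sets as a block all 8 lists passed (highest adjusted p 0.00464). All 8 also passed within the high set (highest 0.0109), but in the low set only myeloid (0.000222) and endothelial genes (0.0341) did, with smooth muscle and fibroblast genes at 0.0926, interferon genes at 0.0923, stress genes at 0.188, skeletal muscle at 0.207 and adipocyte genes at 0.913. B and plasma cell and skin keratinocyte markers passed in the low set only, both down (0.0341 each).

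**Figure D2:**
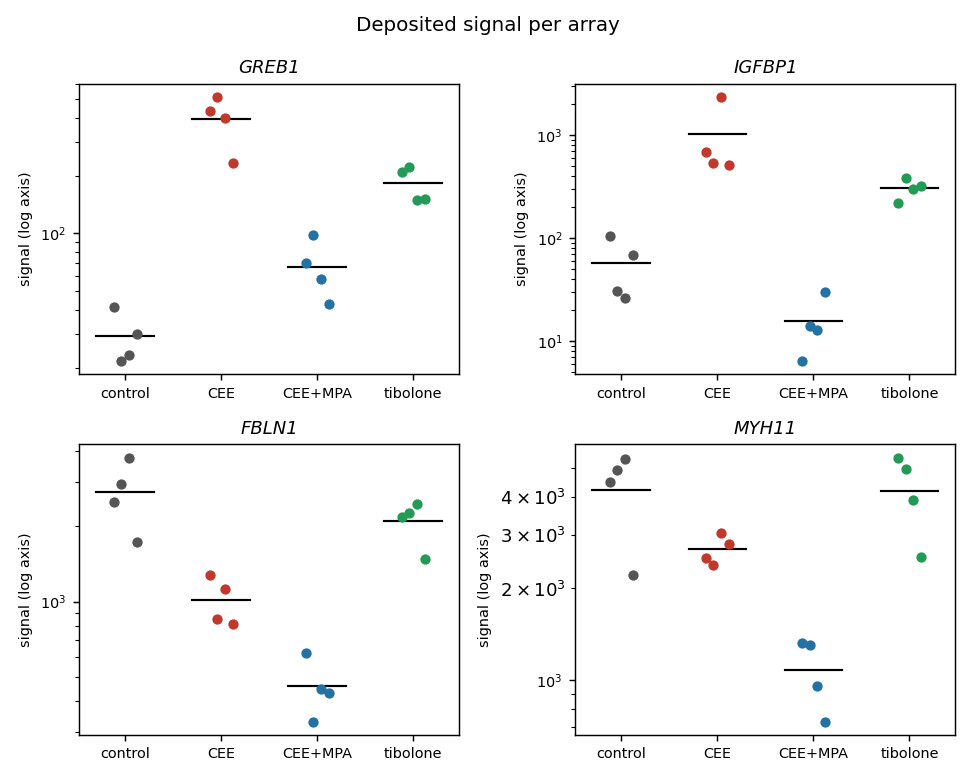
Deposited signal (log axis) of GREB1, IGFBP1, FBLN1 and MYH11 on each of the 16 arrays by group, 1 point per array, with a line at the group mean. Mean GREB1 signal was 29.1 in controls, 394 with CEE, 67.1 with CEE+MPA and 183 with tibolone, and mean FBLN1 signal fell from 2731 in controls to 458 with CEE+MPA.

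The combination of CEE with MPA, a progestin, was compared with no treatment. DLK1, which encodes a Notch-like protein that blocks fat cell formation, rose from a signal of 141 ± 77.0 to 1140 ± 316 (SD, n = 4 each), by 3.06 ± 0.57 (limma, adjusted p = 0.00949). The prolactin pathway genes STAT5A, from 403 ± 223 to 1219 ± 145 (1.71 ± 0.33, adjusted p = 0.0107), and CISH, a target of STAT5 (1.83 ± 0.39, adjusted p = 0.0157), rose as well. RSPO1, which encodes an activator of Wnt signalling, rose by 2.38 ± 0.58 (adjusted p = 0.0286), while its receptor gene LGR5 fell from 540 ± 397 to 34.8 ± 14.5, a change of -3.22 ± 0.61 (adjusted p = 0.00967). FBLN1 fell from 2731 ± 846 to 458 ± 122 (-2.52 ± 0.25, adjusted p = 0.000342) and SPP1, the osteopontin gene, from 9658 ± 2548 to 1335 ± 2068 (-4.13 ± 1.06, adjusted p = 0.0338). GREB1 rose by 0.86 ± 0.24 (adjusted p = 0.0466), less than the 3.15 with CEE alone.

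The remaining genes with the largest rises were RYR2 (2.34), LAMP5 (2.005), C2H3orf18 (1.76) and PADI2 (1.71), and those with the largest falls LOC722305 (-4.65), SAA1 (-4.30), LOC703284 (-4.29), BPIFB1 (-3.06) and WFDC2 (-2.46). DLK1, C2H3orf18, LGR5, BPIFB1, FBLN1 and WFDC2 passed in all 24 alternatives. Leaving out any 1 of the 8 arrays ended the call of at least 3 of RSPO1, PADI2, SPP1, RYR2, LAMP5 and SAA1 (highest adjusted p 0.0807, 0.119, 0.120, 0.125, 0.140 and 0.163). LAMP5 stood at 1.28 without CEE+MPA replicate 2 and at 2.62 without CEE+MPA replicate 1. Without control replicate 2 the calls of CISH (adjusted p = 0.0523), LOC722305 (0.0651) and LOC703284 (0.0811, its highest) ended. That of LOC703284 also ended without control replicate 3, CEE+MPA replicate 2 or CEE+MPA replicate 3, and that of STAT5A on arrays with little skeletal muscle (0.0548). GREB1 missed the threshold in 14 of 23 alternatives, among them the omission of any array but CEE+MPA replicate 4 (highest adjusted p 0.145). With the 3 spike-in sets as steps SAA1 did not pass.

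Of 28716 probe sets, 561 were higher and 1258 lower with CEE+MPA than control, 1819 in all, and 6906 had an unadjusted p under 0.05. They included 286 genes that rose and 518 that fell. The share that was lower, 69.2%, was 50.2% of 1793 with median centring of the arrays and 67.3% of 1323 with quantile normalization. A block for the spike-in sets gave 2373, of which 64.6% were lower. Within the high set (2 against 2 arrays) 425 were higher and 950 lower, and within the low set 0 passed in limma, with 2685 at an unadjusted p under 0.05. All 1819 kept their direction in both sets, which was partly built in. Leaving out 1 array gave 348 (control replicate 2), 552 (CEE+MPA replicate 3), 658 (CEE+MPA replicate 2), 702 (control replicate 1), 1058 (control replicate 3) or 1202 (CEE+MPA replicate 1).

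Smooth muscle genes, which myoepithelial cells also express, fell with CEE+MPA: 11 of the 15 tested members fell and 0 rose over all genes, 13 fell adjusted over the list alone, and the median change was -1.07 (camera adjusted p = 2.13e-09; adjusted p = 0.327 with an estimated correlation). MYH11, the smooth muscle myosin heavy chain gene, fell from 4235 ± 1393 to 1077 ± 288 (-1.92 ± 0.28, adjusted p = 0.00365), SYNPO2 changed by -1.24 ± 0.18, KCNMB1 by -1.39 ± 0.22 and CALD1 by -0.70 ± 0.14. Fibroblast and matrix genes fell, with 8 of 27 lower over all genes and 15 lower and 1 higher adjusted over the list alone (median -0.56, adjusted p = 9.48e-08; 0.327 as adjusted p with an estimated correlation). Members OGN, DPT and SFRP2 changed by -1.81 ± 0.28, -1.94 ± 0.30 and -1.22 ± 0.21. Basal and myoepithelial genes fell (median -0.57 over 17, adjusted p = 0.0240; adjusted p = 0.449 with an estimated correlation): TRIM29 changed by -1.60, ACTG2 by -2.03 and KRT16 by -1.42, all past the threshold, while ITGA6, at 0.73, was not. Over the list alone 6 of these genes were lower and 1 higher. The endothelial list fell (median -0.55 over 19, adjusted p = 3.64e-05; adjusted p = 0.4002 with an estimated correlation), with MMRN1 (-1.42), RAMP2 (-0.73) and ERG (-0.48) lower over all genes, 6 lower over the list alone, and EMCN (-0.58) not past the threshold. The luminal epithelial list did not pass (adjusted p = 0.566).

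Myeloid and interferon response genes also lay lower with CEE+MPA. The interferon list (median -0.50 over 23, adjusted p = 0.000108; adjusted p = 0.449 with an estimated correlation) had 3 members lower over all genes, SAMD9L (-0.63), BST2 (-0.50) and IFI44 (-0.78), with IFI35 (-0.73) not past the threshold, and 7 lower adjusted over the list alone. The myeloid list (median -0.63 over 20, adjusted p = 0.00677; adjusted p = 0.467 with an estimated correlation) had MS4A7 lower (-0.80), with CSF1R at -0.67, C1QB at -0.95 and MRC1 at 0.53 not past the threshold, and 3 lower and 1 higher adjusted over the list alone. Immediate early and stress genes fell as a list (median -0.77 over 19, adjusted p = 0.00812; adjusted p = 0.487 with an estimated correlation), although MYC rose by 1.002 ± 0.27. JUND (-0.86), CCN1 (-1.69) and KLF4 (-1.22) did not pass, and 6 stress genes were lower and 1 higher adjusted over the list alone. Cell cycle genes rose as a list (median 0.69 over 34, adjusted p = 0.000604; adjusted p = 0.721 with an estimated correlation), with GMNN higher (0.91), DLGAP5 lower (-0.76), and CDKN3 (1.35) and CCNE2 (0.59) not past the threshold. Adjusted over the list alone these were also 1 higher and 1 lower. In the IGF list (median -0.38 over 19, adjusted p = 0.0434; adjusted p = 0.449 with an estimated correlation) IGFBP4 (-1.11) and IGFBP3 (-1.55) fell, CISH rose and IGFBP6 (-0.78) did not pass. The Wnt and RANKL list (median -0.30 over 24, adjusted p = 0.0434; adjusted p = 0.327 with an estimated correlation) held falls of LGR5, SFRP2 and WIF1 (-2.45), a secreted Wnt inhibitor gene, and the rise of RSPO1. Adjusted over the list alone 4 IGF genes and 5 Wnt genes were lower and 1 of each higher.

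Among these CEE+MPA lists, the cell cycle list rose in the high set (camera at the preset correlation, adjusted p = 1.34e-07). It did not pass in the low set, where its direction was down (adjusted p = 0.834). The CEE+MPA arrays of the low set had list means of 0.65 (replicate 1) and -1.14 (replicate 4). Both CEE+MPA arrays of the high set had 0.96 and 0.89, so replicate 4 alone stood low, and without it the list had an adjusted p of 1.3e-13. Smooth muscle genes fell in both sets (low 2.88e-08, high 4.97e-07), as did fibroblast genes (0.000895, 3.67e-08), endothelial genes (0.0398, 1.34e-07), interferon genes (0.00122, 0.00130) and stress genes (0.0372, 0.0257). Myeloid genes passed in the high set (0.0152; low 0.0722), IGF genes in the high set (0.0257; low 0.279), and basal genes (0.0102; high 0.153) and Wnt genes (0.0297; high 0.217) in the low set. Lists that did not pass over all arrays but did in 1 set, all down, were adipocyte (0.000218), skeletal muscle (0.0257) and Schwann cell and nerve genes (0.0352) in the high set, and estrogen response (0.0297) and skin keratinocyte genes (0.0398) in the low set. With the sets as a block all 10 lists passed (highest adjusted p 0.0461). With fry 7 of the 10 passed, smooth muscle (0.00123), fibroblast (0.00345), Wnt (0.00989), endothelial (0.0156), IGF (0.0292), basal (0.0390) and interferon genes (0.0479), and the myeloid (0.0753), stress (0.0893) and cell cycle lists (0.313) did not. The IGF list missed the threshold without control replicate 1 (0.0658), 2 (0.0585) or 4 (0.0558) or CEE+MPA replicate 2 (0.0697), 3 (0.0888) or 4 (0.0721). So did the Wnt list without control replicate 3 (0.0803) or CEE+MPA replicate 3 (0.0981) or 4 (0.0721), the basal list without control replicate 3 (0.0528) or CEE+MPA replicate 4 (0.0721), and the stress list without control replicate 1 (0.0999). With the mean of each gene's probe sets the basal and Wnt lists stood at 0.0602 and 0.0841. Some members named above lost their calls when 1 array was left out: IFI44 without any 1 of the 8 arrays (highest 0.125), BST2 likewise (0.127), MYC without any 1 but control replicate 1 and CEE+MPA replicate 4 (0.147), and IGFBP3 without any 1 but control replicate 4 and CEE+MPA replicate 4 (0.146). GMNN (0.127), DLGAP5 (0.113), SAMD9L (0.107), MMRN1 (0.108), RAMP2 (0.126) and ERG (0.143) were each lost in 8 to 11 alternatives, for all 6 including control replicate 1 and CEE+MPA replicate 2 left out. KRT16 (highest adjusted p 0.106), MS4A7 (0.0760), TRIM29 (0.0615), CALD1 (0.0582) and ACTG2 (0.0547) were lost in 1 to 7 alternatives, all 5 without control replicate 2.

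**Figure D3:**
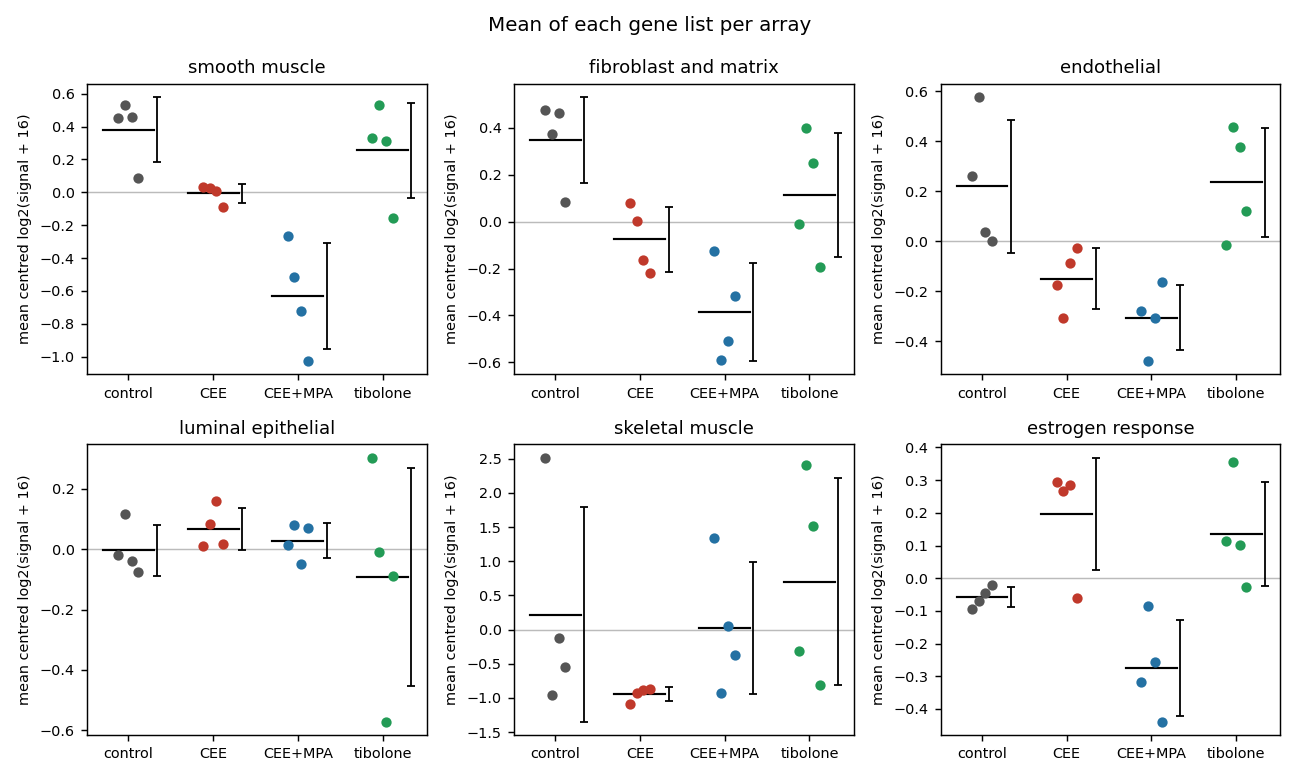
Mean over the genes of 6 lists on each of the 16 arrays by group, as log2(signal + 16) centred on each gene's mean over all arrays, with 1 point per array, a line at the group mean and a bar of 1 SD to each side. The smooth muscle mean was 0.38 in controls and -0.63 with CEE+MPA, and the skeletal muscle mean exceeded 1 on 4 arrays.

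The means of 15 lists on each array were compared between groups. The smooth muscle mean was -0.63 ± 0.32 with CEE+MPA, -0.01 ± 0.06 with CEE, 0.26 ± 0.29 with tibolone and 0.38 ± 0.20 in controls (SD, n = 4 each). CEE+MPA differed from each of the other 3 groups, and CEE from control, with an exact permutation p of 0.0286, the smallest that 4 against 4 arrays allow. Fibroblast, endothelial and myeloid means were also lower with CEE and with CEE+MPA than in controls at an exact permutation p of 0.0286. At the same p, basal means were lower with CEE+MPA than in controls (difference -0.47) and than with CEE (-0.39), and estrogen response means lower with CEE+MPA than with CEE (-0.47). It was also reached by estrogen response and endothelial means between tibolone and CEE+MPA (0.41 and 0.54) and by skeletal muscle and endothelial means between tibolone and CEE (1.64 and 0.38). Skin keratinocyte (-0.50) and Schwann cell and nerve means (-0.46) were lower with CEE+MPA than in controls at that p. Both were higher with tibolone than with CEE+MPA (0.40 and 0.35) at that p. The remaining tests of lists past the camera threshold did not reach it: adipocyte and skeletal muscle means between CEE and control (exact permutation p = 0.200 and 0.114), and cell cycle means between CEE+MPA and control (0.229), CEE+MPA and CEE (0.514) and tibolone and control (0.314). Nor did fibroblast means between tibolone and control (0.200), CEE+MPA and CEE (0.0857) or tibolone and CEE+MPA (0.0571), skeletal muscle means between CEE+MPA and CEE (0.0857), or myeloid and adipocyte means between tibolone and CEE (0.114 and 0.343). The luminal epithelial mean differed between CEE+MPA and control by 0.03 (exact permutation p = 0.571). None of the 90 such tests passed after adjustment (lowest adjusted p = 0.122). The first principal component, with 26.2% of the variance, parted CEE+MPA from each of the other groups and CEE from control (exact permutation p = 0.0286 each). It did not part tibolone from CEE (exact permutation p = 0.114). On it tibolone replicate 4 lay at 16.9, within the CEE range of 12.4 to 23.2, and the other tibolone arrays at -59.4 to -16.8. The highest correlation of tibolone replicate 4 with another array, 0.9603, equalled that of CEE replicate 4. Its median correlation within its group, 0.925, was the lowest of all arrays.

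Tibolone was compared with no treatment. GREB1 rose from 29.1 ± 8.95 to 183 ± 38.2 (SD, n = 4 each), by 2.14 ± 0.24 (limma, adjusted p = 0.00163), and every tibolone array lay above every control array. It was the only gene past the threshold under the naming rule, and it passed with the spike-in sets as a block (2.16, adjusted p = 0.0107) but not on arrays with little skeletal muscle (adjusted p = 0.141). IGFBP1 had a signal of 306 ± 68.7 against 57.8 ± 36.9 without passing (2.23 ± 0.43, adjusted p = 0.124). TTC36 (2.55, adjusted p = 0.101), CHAD, a cartilage matrix gene (1.90, adjusted p = 0.115), CHI3L2 (-1.67, adjusted p = 0.199), KLHL13 (-0.76, adjusted p = 0.237) and C1QTNF3 (-1.17, adjusted p = 0.350) did not pass either. In all 7 probe sets were higher and 0 lower, 4 of them without a symbol, and 1552 had an unadjusted p under 0.05 where 1436 would by chance. With the spike-in sets as a block 4 passed, and within the high set (4 against 2 arrays) 2 did. The count was 4 without tibolone replicate 2 or tibolone replicate 3, and 0 on arrays with little skeletal muscle, with 2205 at an unadjusted p under 0.05 there.

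Cell cycle genes rose as a list with tibolone (median 0.44 over 34, camera adjusted p = 0.00154; adjusted p = 0.902 with an estimated correlation) and IGF genes rose (0.19 over 19, adjusted p = 0.0124; adjusted p = 0.529 with an estimated correlation). Milk and secretory genes fell (-0.44 over 22, adjusted p = 0.00154; adjusted p = 0.529 with an estimated correlation), as did fibroblast and matrix genes (-0.26 over 27, adjusted p = 0.00300; adjusted p = 0.689 with an estimated correlation). The milk mean was low on tibolone replicates 3 (-1.16) and 4 (-0.74) but not on replicates 1 (0.34) and 2 (-0.01), and tibolone replicate 3 also had the lowest luminal epithelial mean (-0.57, against -0.09 to 0.30 on the other tibolone arrays). With fry none of the 4 lists passed (lowest adjusted p 0.246). No member passed over all genes, and adjusted over the list alone 2 IGF genes were higher. Members with the smallest p were the replication genes MCM4 (0.45), MCM2 (0.47) and MCM5 (0.61) with CCNE2 (0.37), then IRS1 (1.14), IGF1R (0.53) and CISH (0.90) beside IGFBP1. In the milk list these were LPO (-0.93), SLC30A2 (-0.87), OLAH (-1.76) and FOLR1 (-1.41), and in the matrix list COL1A1 (-0.80), OGN (-0.69), DPT (-0.66) and COL6A3 (-0.34). With the spike-in sets as a block only the IGF list passed (0.0106), with cell cycle and milk genes at 0.0667 and matrix genes at 0.133. Within the high set the cell cycle list passed (3.04e-05), as did milk (0.0172) and matrix genes (0.000932), and the IGF list did not (0.174). Adipocyte and endothelial genes (0.0139 each), smooth muscle genes (0.0172) and Schwann cell and nerve genes (0.0375) also passed there, all down, though not over all arrays. The cell cycle list missed the threshold without control replicate 2 (0.0948) or tibolone replicate 1 (0.230), the milk list without tibolone replicate 3 (0.223), the matrix list without tibolone replicate 4 (0.165), and the IGF list without tibolone replicate 2 (0.235) or 3 (0.0649).

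CEE+MPA was compared with CEE alone, which addresses the effect of adding MPA to the same dose of estrogen. IGFBP1 fell from 1019 ± 885 to 15.9 ± 10.1 (SD, n = 4 each), a change of -4.76 ± 0.43 (limma, adjusted p = 0.000212). GREB1 fell from 394 ± 118 to 67.1 ± 23.2, a change of -2.29 ± 0.24 (adjusted p = 0.000645), and BCAS1 from 143 ± 40.9 to 27.9 ± 12.2, a change of -1.86 ± 0.22 (adjusted p = 0.00269). All 3 passed in every alternative, and their CEE+MPA arrays did not overlap the CEE arrays. Within the low and the high spike-in sets IGFBP1 differed by -4.27 and -5.25, and GREB1 by -2.77 and -1.81. No gene was higher past the threshold, and CLHC1 (1.13, adjusted p = 0.134), NARS2 (0.66, adjusted p = 0.203) and LAMP5 (2.47, adjusted p = 0.243) had the smallest p. In all 6 probe sets were lower and 0 higher, and 2217 had an unadjusted p under 0.05. With the sets as a block 5 passed, within the low set 1, and within the high set 0 in limma, with 2523 at an unadjusted p under 0.05. The count was 13 without CEE replicate 4, 13 with a skeletal muscle covariate and 13 on arrays with little skeletal muscle.

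The estrogen response list fell with CEE+MPA relative to CEE (median -0.29 over 36, camera adjusted p = 4.76e-05; adjusted p = 0.0760 with an estimated correlation), with GREB1 lower over all genes and 9 lower adjusted over the list alone. TFF3, an estrogen-raised secreted peptide gene, had signals of 96.4 ± 37.5 with CEE+MPA and 1461 ± 1274 with CEE without passing (-3.25 ± 0.66, adjusted p = 0.177), and RERG (-1.04) and RBBP8 (-0.94) did not pass. The IGF list fell (-0.30 over 19, adjusted p = 0.000102; adjusted p = 0.0760 with an estimated correlation) with IGFBP1 lower over all genes, 4 lower adjusted over the list alone, and IRS1 (-1.11), IGFBP4 (-0.77) and IGFBP3 (-1.40) not past the threshold. Smooth muscle genes fell (-0.77 over 15, adjusted p = 1.56e-09; adjusted p = 0.111 with an estimated correlation), with 0 past the threshold over all genes and 9 lower adjusted over the list alone, among the named members MYH11 (-1.34), SYNPO2 (-0.77), TAGLN (-0.97) and KCNMB1 (-0.86). Fibroblast and matrix genes fell (-0.29 over 27, adjusted p = 0.000105; adjusted p = 0.407 with an estimated correlation; 1 lower over the list alone), with FBLN1 at -1.14, SFRP4 at -1.22, COL3A1 at -0.43 and SFRP2 at -0.55. Basal genes fell (-0.32 over 17, adjusted p = 0.00155; adjusted p = 0.249 with an estimated correlation; 2 lower over the list alone), with TRIM29 at -1.39, ACTG2 at -1.48, KRT16 at -0.97 and S100A2 at -0.56. No member of these 3 lists passed over all genes.

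Interferon genes also fell relative to CEE (-0.23 over 23, adjusted p = 0.0369; adjusted p = 0.581 with an estimated correlation), with PARP14 (-0.36), ISG15 (-0.43), BST2 (-0.24) and MX2 (-0.38) not past the threshold. Cell cycle genes rose as a list (0.47 over 34, adjusted p = 0.000209; adjusted p = 0.581 with an estimated correlation), with GMNN at 0.67, CDC6 at 0.72, CDCA8 at 0.67 and DLGAP5 at -0.53. Skeletal muscle genes rose (0.97 over 17, adjusted p = 0.00154; adjusted p = 0.581 with an estimated correlation), with MYL1 at 3.17, ACTN2 at 1.03, ATP2A1 at 1.32 and CKM at 1.48, and so did milk genes (0.24 over 22, adjusted p = 0.0213; adjusted p = 0.487 with an estimated correlation), with BTN1A1 at 1.67, SLC30A4 at 0.52, PAEP at 0.95 and FABP3 at 1.13. No member of these 4 lists passed over all genes or adjusted over the list alone. With fry the estrogen response and IGF lists (0.0123 each) and smooth muscle genes (0.0221) passed, and basal (0.103), fibroblast (0.218) and milk genes (0.491) and the other 3 lists (0.536 each) did not. With the spike-in sets as a block all 9 lists passed (highest adjusted p 0.0359). Within the low and high sets smooth muscle (1.21e-06, 0.000139), IGF (0.00276, 0.00641) and matrix genes (0.0311, 0.00375) passed in both. Estrogen response (1.21e-06; high 0.135), basal (0.000500; high 0.260), skeletal muscle (0.000219; high 0.469) and milk genes (0.0187; high 0.330) passed in the low set. Cell cycle genes passed in the high set (1.56e-09; low 0.609, where their direction was down and CEE+MPA replicate 4 had a mean of -1.14), and interferon genes in neither (0.123, 0.244). Endothelial genes (down, 0.00375) and unfolded protein and secretory pathway genes (up, 0.0377) passed in the high set alone. The milk list missed the threshold without CEE replicate 1 (0.0580) or 4 (0.228) or CEE+MPA replicate 1 (0.102) or 4 (0.126) and with quantile normalization (0.0812). The interferon list missed it without CEE replicate 2 (0.560) or CEE+MPA replicate 2 (0.106) or 3 (0.277) and with quantile normalization (0.0605), the skeletal muscle list without CEE+MPA replicate 1 (0.187) and the cell cycle list without CEE+MPA replicate 2 (0.0560).

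Tibolone was compared with CEE, and no gene passed under the naming rule. GREB1 had a signal of 183 ± 38.2 with tibolone and 394 ± 118 with CEE (SD, n = 4 each), a difference of -1.01 ± 0.24 (limma, adjusted p = 0.218). HSD3B2, a steroid synthesis gene, had 201 ± 151 against 6.11 ± 4.76 (3.07 ± 0.50, adjusted p = 0.0725), and PON2 (0.83) and FST (0.95) were the other genes with the smallest p among higher values. OPA1, a mitochondrial fusion gene (-0.69, adjusted p = 0.0725), MCCD1 (-1.78, adjusted p = 0.0725) and LYRM9 (-0.80, adjusted p = 0.145) had the smallest p among lower values. Of the probe sets, 1 was higher, MmugDNA.34701.1.S1_at without a symbol, and 1 lower, a TMPRSS3 probe set with a lower mean log2 signal than the one that represented its gene. Both were named after their values were seen. At an unadjusted p under 0.05 there were 3424. The count was 0 with the spike-in sets as a block (2944 unadjusted), 1 within the high set (4 against 2 arrays), 0 without CEE replicate 1 (2944 unadjusted), 4 without tibolone replicate 1, 7 without CEE replicate 3 and 238 without tibolone replicate 4. It was 0 with a skeletal muscle covariate (1878 unadjusted) and 0 on arrays with little skeletal muscle (1444 unadjusted).

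Skeletal muscle genes lay higher with tibolone than CEE (median 1.76 over 17, camera adjusted p = 1.28e-05; adjusted p = 0.610 with an estimated correlation), with TNNT3 at 1.78, MYL1 at 3.89, MYH2 at 2.54 and MYBPC1 at 2.12. Endothelial genes (0.31 over 19, adjusted p = 0.000208), myeloid genes (0.60 over 20, adjusted p = 0.000401) and stress genes (0.48 over 19, adjusted p = 0.00722) rose as lists, each at adjusted p = 0.610 with an estimated correlation. Adipocyte genes (0.50 over 27, adjusted p = 0.00480) and interferon genes (0.32 over 23, adjusted p = 0.00722) rose too, each at adjusted p = 0.617 with an estimated correlation. With fry none of the 6 passed (lowest adjusted p 0.184). No member of the 6 lists passed over all genes, and 1 interferon gene was higher adjusted over the list alone. Named members were EGFL7 (0.85), CLDN5 (0.69), RAMP2 (0.51) and PROX1 (0.87) of the endothelial list, CLEC7A (0.64), C1QB (0.87), CD68 (0.70) and TYROBP (0.56) of the myeloid list, and RETN (0.69), CFD (0.94), GPAM (0.71) and MRAP (1.05) of the adipocyte list. IRF7 (1.28), OAS2 (0.59), SAMD9L (0.50) and BST2 (0.34) of the interferon list, and BTG2 (0.77), IER2 (0.76), JUND (0.71) and HSPH1 (0.64) of the stress list, did not pass either. With the spike-in sets as a block the stress list did not pass (0.104) and the other 5 did (highest 0.00109). The same 5 passed within the high set (highest 0.000876; stress genes 0.0799), and so did fibroblast and matrix (0.00028) and smooth muscle genes (0.0394), both up, which had not passed over all arrays. Adipocyte genes missed the threshold without CEE replicate 4 (0.149) or tibolone replicate 3 (0.210), and interferon genes without CEE replicate 4 (0.119) or tibolone replicate 4 (0.147).

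Tibolone was compared with CEE+MPA, the other regimen with progestogenic activity. IGFBP1 rose from 15.9 ± 10.1 to 306 ± 68.7 (SD, n = 4 each), by 3.36 ± 0.43 (limma, adjusted p = 0.00247), and GREB1 from 67.1 ± 23.2 to 183 ± 38.2, by 1.28 ± 0.24 (adjusted p = 0.0130). FBLN1 rose from 458 ± 122 to 2092 ± 428 (2.16 ± 0.25, adjusted p = 0.00143) and MYH11 from 1077 ± 288 to 4198 ± 1272 (1.93 ± 0.28, adjusted p = 0.00428), to means close to the control signals of 2731 and 4235. LGR5 rose by 2.64 ± 0.61 (adjusted p = 0.0248), LOC701220 by 3.36 ± 0.49 (adjusted p = 0.00399), and LOC722305 and ZG16B by 3.76 and 2.68. The genes with the largest falls were KMO, which encodes a kynurenine pathway enzyme (-2.56 ± 0.73), the growth factor gene EGF (-2.46 ± 0.61), DLK1 (-2.28 ± 0.57), SLC6A15 (-2.20 ± 0.49) and VEPH1 (-2.20 ± 0.46). In all 1086 probe sets were higher and 734 lower, 1820 of 28716, and 7203 had an unadjusted p under 0.05. They included 416 genes that rose and 352 that fell.

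This contrast of tibolone with CEE+MPA depended on the scaling, on the groups in the model and on single arrays. Its count fell with only these 2 groups fitted, as given with the alternatives below. The median SD within a group was 0.281 with tibolone, 0.258 with CEE+MPA, 0.246 with CEE and 0.239 in controls. The main model pooled these 4 groups. The share lower was 40.3%, but 72.4% of 2131 with median centring and 47.7% of 1301 with quantile normalization. The median signal differed between the groups (63.2 with tibolone, 57.6 with CEE+MPA, exact permutation p = 0.0286). A block for the spike-in sets gave 735, of which 29.4% were lower, and within the high set (4 against 2 arrays) 425 were higher and 139 lower, on arrays that differed in spike-in level between the groups. With 3 spike-in sets as steps 2431 passed, of which 42.4% were lower. Leaving out 1 array gave 209 (tibolone replicate 2), 295 (tibolone replicate 3), 413 (CEE+MPA replicate 3), 723 (CEE+MPA replicate 1), 843 (CEE+MPA replicate 2), 1040 (CEE+MPA replicate 4) or 3333 (tibolone replicate 4). The count was 747 with a skeletal muscle covariate, and 0 on arrays with little skeletal muscle, which kept 2 tibolone arrays, with 2848 at an unadjusted p under 0.05. IGFBP1, FBLN1, MYH11 and LOC701220 missed the threshold only on those arrays (adjusted p = 0.111, 0.0907, 0.163 and 0.147), and GREB1 there (0.252) and without tibolone replicate 2 (0.0517). KMO, EGF, DLK1, SLC6A15, LGR5 and LOC722305 missed it with the sets as a block (0.111, 0.0707, 0.0859, 0.0586, 0.0610 and 0.0930) and without either tibolone replicate 2 or 3 (highest over all alternatives 0.186, 0.458, 0.534, 0.452, 0.401 and 0.563). So did ZG16B without any CEE+MPA array or tibolone replicate 2 or 3 (highest 0.356), and VEPH1 without tibolone replicate 2 or 3 (highest 0.405).

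Smooth muscle genes were higher with tibolone than CEE+MPA, 8 of 15 over all genes and 11 adjusted over the list alone (median 0.96, camera adjusted p = 7.25e-07; adjusted p = 0.330 with an estimated correlation), with SYNPO2 at 1.06 ± 0.18, KCNMB1 at 1.28 ± 0.22 and ACTG2 at 1.93 ± 0.44. Endothelial genes rose (0.58 over 19, adjusted p = 8.66e-05; adjusted p = 0.346 with an estimated correlation), with RAMP2 (0.72) and CLDN5 (0.85) higher over all genes and 8 higher adjusted over the list alone, and VWF (0.90) and EGFL7 (0.85) not past the threshold. Fibroblast and matrix genes rose (0.37 over 27, adjusted p = 0.000444; adjusted p = 0.392 with an estimated correlation), 7 over all genes and 8 over the list alone, among them SFRP2 (0.99), COL6A2 (0.89) and COL6A1 (0.66). IGF genes rose (0.69 over 19, adjusted p = 0.000789; adjusted p = 0.311 with an estimated correlation), 6 over all genes, with IRS1 at 1.53, IGFBP6 at 1.14 and IGFBP3 at 1.96, and 9 higher and 2 lower adjusted over the list alone. Interferon genes rose (0.37 over 23, adjusted p = 0.000789; adjusted p = 0.392 with an estimated correlation), with PARP14 (0.79), BST2 (0.57) and IRF7 (1.24) past the threshold over all genes, ISG15 (0.80) not, and 8 higher over the list alone.

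The stress list rose too (0.74 over 19, adjusted p = 0.00672; adjusted p = 0.392 with an estimated correlation), with JUND (1.16) past the threshold over all genes, JUNB (1.49), BTG2 (0.73) and IER2 (0.75) not, and 2 higher adjusted over the list alone. Estrogen response genes rose (0.29 over 36, adjusted p = 0.00957; adjusted p = 0.330 with an estimated correlation), 8 higher and 1 lower over all genes, and 11 higher and 1 lower adjusted over the list alone. Examples were SERPINA3 (1.69) and CXCL12 (1.202), and FKBP4, a steroid receptor chaperone gene, was lower (-0.67). Milk and secretory genes fell relative to CEE+MPA (-0.50 over 22, adjusted p = 0.0112; adjusted p = 0.392 with an estimated correlation), with ELF5, a transcription factor gene of milk-forming epithelium (-1.31), STAT5A (-1.24) and MUC15 (-1.34) lower over all genes, SLC30A2 (-1.11) not, and 4 lower adjusted over the list alone. With fry IGF (0.00108), smooth muscle (0.00278), estrogen response (0.00913), endothelial (0.0117) and fibroblast genes (0.0199) passed, and interferon (0.0549), stress (0.0565) and milk genes (0.0654) did not. With the spike-in sets as a block the milk list did not pass (0.0567), and within the high set, where spike-in levels differed between the groups, neither it (0.227) nor the stress list (0.0808) passed, while the other 6 did (highest 0.0453). Lists that passed there and not over all arrays were cell cycle genes, down (0.000125), and adipocyte (0.00534), myeloid (0.0275) and skeletal muscle genes (0.0282), all up. The milk list also missed the threshold without tibolone replicate 3 (0.0913), the array with the lowest milk and luminal epithelial means. Of the members named for these lists, IRS1 lost its call only on arrays with little skeletal muscle (adjusted p = 0.325), and SYNPO2 (0.181) and KCNMB1 (0.200) there and with the 2 groups fitted alone. Each of the other members past the threshold also lost it in 4 to 17 alternatives, without tibolone replicate 2 in every case (highest 0.642, MUC15).

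Responses to different treatments against the same controls share those 4 arrays, which alone gives a correlation across probe sets. Across 28716 probe sets, which are not independent replicates, the CEE and CEE+MPA responses had a Pearson r of 0.74 where unchanged groups simulated with shared controls gave 0.50, and a covariance of 0.120 against 0.0318. With 2 controls for each treatment, r was 0.46 on average over 6 divisions (0.34 to 0.54). The CEE and tibolone responses had an r of 0.42 (simulated 0.50), a covariance of 0.0436 (simulated 0.0317) and a mean r of 0.10 with divided controls (-0.13 to 0.23). For CEE+MPA and tibolone these were 0.31 (simulated 0.50), 0.0403 (simulated 0.0317) and 0.07 (-0.18 to 0.25). The simulation held no spike-in sets, while all 4 tibolone arrays lay in the high set and each other group was divided 2 and 2. A difference between the sets can thus enter the tibolone responses. These lower values do not tell it from a different response to tibolone. CEE and CEE+MPA shared 4 probe sets that were higher and 7 lower, CEE and tibolone 3 that were higher, and CEE+MPA and tibolone 1. Shared controls alone can raise such counts. In 20 simulations of unchanged groups with shared controls, each group had 0.05 calls on average and 0 were shared. So few calls leave almost no room for sharing, and the amount for groups with a response was not measured.

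Of the fixed panel, GREB1 is described with each comparison. The progesterone receptor gene PGR had signals of 17.7 ± 3.67 in controls, 88.7 ± 49.5 with CEE, 17.6 ± 8.86 with CEE+MPA and 75.1 ± 73.4 with tibolone (SD, n = 4 each), and passed in none of the 6 comparisons (CEE against control 1.51 ± 0.48, limma, adjusted p = 0.242). In tibolone against CEE+MPA it stood at 1.08 (adjusted p = 0.175), at 0.59 without tibolone replicate 2 (adjusted p = 0.450), which had the highest PGR signal of all arrays (179), and at 1.64 without tibolone replicate 4, where it passed (adjusted p = 0.0147). The cell cycle genes MKI67 and TOP2A had signals of 258 ± 144 and 1213 ± 840 with CEE+MPA and 118 ± 27.7 and 324 ± 142 in controls. They did not pass (0.82 ± 0.43, adjusted p = 0.257, and 1.32 ± 0.76, adjusted p = 0.310) but did without CEE+MPA replicate 4 (adjusted p = 0.0266 and 0.0202). With 1 array left out they stood at 0.58 to 1.34 and 0.88 to 2.30, and at -0.05 and -0.03 in the low set, which holds that array, against 1.70 and 2.66 in the high set. PRLR and KRT18 passed only in tibolone against CEE+MPA and only without tibolone replicate 4 (adjusted p = 0.0296 and 0.0471). WNT4, AREG and ADIPOQ passed in no comparison, with log2 fold changes against control of 0.71, 0.70 and -0.32 for CEE, 1.01, 0.83 and -0.52 for CEE+MPA, and 0.72, 0.38 and 0.49 for tibolone. In the low and high sets AREG stood at -0.25 and 1.64 for CEE and -0.74 and 2.41 for CEE+MPA, ADIPOQ at 0.94 and -1.58 and at 0.89 and -1.93, and WNT4 at 0.21 and 1.21 and at 0.49 and 1.52. With 1 array left out, AREG stood at 0.29 (without control replicate 2) to 1.13 (control replicate 4) for CEE, 0.40 (CEE+MPA replicate 2) to 1.27 (control replicate 4) for CEE+MPA and -0.03 (control replicate 2) to 0.82 (control replicate 4) for tibolone. ADIPOQ then stood at -0.83 (without control replicate 3) to 0.21 (CEE replicate 4) for CEE, -1.04 (control replicate 3) to -0.03 (CEE+MPA replicate 2) for CEE+MPA and -0.02 (control replicate 3) to 1.05 (tibolone replicate 4) for tibolone. WNT4 stood at 0.61 to 0.98 for CEE, 0.85 to 1.28 for CEE+MPA, and 0.23 (without tibolone replicate 2) to 1.18 (tibolone replicate 3) for tibolone. ESR1, TNFSF11 and FKBP5 lay below the filter, and TFF1 was not in the annotation table.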

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

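The tests of the scaling, of stromal cells, of skeletal muscle, of luminal epithelium and of the CEE response with the CEE+MPA arrays divided, and the counts over other splits of the arrays, were chosen only after the results were seen. Those of regression to the mean, of the spread among CEE arrays and of a smaller CEE response with only the controls divided were written before.

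A single array stood apart from the other 3 of its group in 3 of 76 groups of array-level values and 35 of 588 groups of gene values, by Dixon's test of the gap to the nearest array, where chance gives about 5%. The cell cycle mean of CEE+MPA replicate 4 was -1.14 against 0.65 to 0.96 on the other CEE+MPA arrays, and its B and plasma cell mean was -0.39 against 0.13 to 0.17. The estrogen response mean of CEE replicate 4 was -0.061 against 0.27 to 0.29 on the other CEE arrays.

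Gene values that stood apart are given as log2(signal + 16). On CEE+MPA replicate 4 these were CDCA8 at 6.87, CDKN3 at 6.43, GMNN at 8.25 and RBBP8 at 8.24, all below the other CEE+MPA arrays. On CEE+MPA replicate 1 CALD1 was high at 12.28 and JUND low at 7.67, and on CEE+MPA replicate 3 ISG15 was low at 7.81. On control replicate 1 the muscle genes ATP2A1 and TNNT3 were high at 8.21 and 10.89, and PAEP was high at 9.84. On control replicate 2 CFD was high at 13.62 and DLK1 low at 5.47. On control replicate 3 GPAM and MRAP were low at 10.19 and 5.71 and IGFBP4 high at 12.17. On control replicate 4 C2H3orf18 (7.89), HSD3B2 (6.58), MS4A7 (9.90) and WNT4 (7.45) were high and RETN (7.33) low. On CEE replicate 1 CXCL9 (6.27) and SFRP4 (12.46) were high, and STAT5A (9.78) and WNT4 (6.66) low. On CEE replicate 2 KRT16 was high at 9.91 and RERG low at 6.82, on CEE replicate 3 CLHC1 was high at 7.33, and on CEE replicate 4 CALD1 was high at 12.49. On tibolone replicate 1 CHAD and COL1A1 were low at 6.62 and 11.03, and on tibolone replicate 2 COL6A3 and FST were high at 12.18 and 9.23. FKBP4 was low on tibolone replicate 3 at 10.03, and on tibolone replicate 4 LOC703284 was low at 5.12 and RYR2 high at 10.06.

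More probe sets were lower than higher with CEE+MPA against control, 69.2% of those past the threshold. Skeletal muscle in some tissue pieces is argued against as the whole cause, since the share was 70.1% with the skeletal muscle mean as a covariate. The scaling of the arrays stays open, because the share was 50.2% with median centring and 67.3% with quantile normalization. Fewer stromal cells of all kinds may contribute: the smooth muscle mean differed by -1.01 and the endothelial mean by -0.53, and the difference between these (-0.49) had an exact permutation p of 0.0857, which decides neither way. Fibroblast, myeloid, and Schwann cell and nerve means differed by -0.73, -0.55 and -0.46 (exact permutation p = 0.0286 each). T and NK cell means (-0.10, exact permutation p = 0.257) and adipocyte means (-0.46, 0.314) did not part the groups. The luminal epithelial mean differed by 0.03 (exact permutation p = 0.571). An effect of the treatment on these genes stays open beside the scaling and the stromal cells.

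GREB1, BCAS1 and IGFBP1 rose with CEE and lay lower with CEE+MPA than with CEE, and in all 6 probe sets were higher in the first and lower in the second comparison, which share the CEE arrays. Across probe sets the responses had an r of -0.08, where sharing alone gave -0.50 in simulation, and a covariance of -0.0092 against -0.0318. With 2 CEE arrays for each response, r was positive, 0.16 on average over 6 divisions (0.11 to 0.25), and the mean covariance was 0.0226. Across all probe sets the 2 responses thus did not tend to oppose each other once the shared arrays were divided. Less luminal epithelium with CEE+MPA is argued against, since the luminal mean differed from that with CEE by -0.038. Regression to the mean through the shared arrays does not act on CEE arrays left out of the choice of probe sets. On average over 6 choices, 20 probe sets chosen on 2 CEE arrays lay lower with CEE+MPA than on the other 2 by a median of -0.59. In single choices the median was -0.16 to -1.12, with 13 to 17 of the 20 lower. A fall thus remained without that regression, but its size, and the part due to regression, are not settled. A response to MPA stays open for GREB1, BCAS1 and IGFBP1, whose CEE+MPA arrays did not overlap their CEE arrays.

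CEE+MPA had 1819 probe sets past the threshold against control, and CEE 21. The median SD within CEE was 0.955 of that within CEE+MPA. That ratio does not test a larger spread among CEE arrays as the cause of these counts. The model gave each probe set the same error, pooled over the 4 groups, in both comparisons. For 500 probe sets chosen on all CEE+MPA arrays and 2 controls, the median CEE response against the other 2 controls was 0.473 of the CEE+MPA response on average over 6 choices (0.372 to 0.542), a ratio lowered by choosing on the arrays of its denominator. Chosen on 2 CEE+MPA arrays and 2 controls and set against the other 2 of each, it was 0.576 on average over 36 choices (0.402 to 0.787), which is consistent with a CEE response of the same direction and smaller size. That is a hypothesis tested on the same arrays: probe sets chosen on CEE+MPA favour those that respond more to it, and a shared feature of the treated arrays is not parted from a response.

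Other splits of the 8 arrays of each comparison into 4 and 4 were counted, 35 in each with the real one. For CEE against control 1 split, the real one, gave as many calls (21, highest other 1). The same held for CEE+MPA against control (1819, highest other 10), CEE+MPA against CEE (6, highest other 2) and tibolone against CEE+MPA (1820, highest other 59). That is the smallest share that 35 splits allow, without adjustment over the 6 comparisons. In the other splits the treatment difference adds to the spread, which lowers their calls. The real counts thus exceeded those of the other splits, but chance cannot be excluded on that ground. For tibolone against control 2 splits gave at least the real 7, and the highest other, with 16, set control replicates 1 and 2 and tibolone replicates 2 and 3 against the rest. For tibolone against CEE 4 splits gave at least the real 2 (highest other 4). Chance is also not excluded for these 2 tibolone counts, where the real split did not give the most calls. The splits that follow the spike-in sets gave 0 calls for CEE against control (21 real), 0 for CEE+MPA against control (1819) and 1 for CEE+MPA against CEE (6) in limma. There too the treatment difference adds to the spread and lowers the calls, so these counts do not show that the sets had no effect. With group in the model, 693 probe sets differed between the sets over all 16 arrays.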

How the results depend on the processing

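The skeletal muscle and spike-in alternatives and the GAPDH coding were chosen after seeing the data. No called gene reversed under any alternative, and of 3161 gene values followed, 47 uncalled ones changed sign. Unless said, the cause of a moved count was not tested. In CEE against control the count of 21 became 10 with no filter, 66 with only the 2 groups compared, 140 with array weights, 99 at a threshold of 0.10, 50 with an offset of 64, 57 with the 3 prime to 5 prime covariate, 8 with the skeletal muscle covariate, 33 with 2 spike-in sets, 38 with 3 and 39 with the GAPDH sets. In CEE+MPA against control 1819 became 984 with no filter, 3729 with array weights, 3714 at 0.10, 1141 with 1 probe set per gene (fewer tests) and 980 on arrays with little skeletal muscle (fewer arrays). In tibolone against control 7 became 4 with only the 2 groups, 11 with array weights, 1 with 1 probe set per gene, 4 with the luminal covariate, 4 with 2 or 3 spike-in sets and 0 with little skeletal muscle. In CEE+MPA against CEE 6 became 11 with a trended prior, 12 with only the 2 groups, 14 with array weights, 15 at 0.10, 3 with 1 probe set per gene, 11 with the 3 prime to 5 prime covariate and 13 with either skeletal muscle alternative. In tibolone against CEE 2 became 7 with a stricter filter, 6 with a trended prior, 1 with only the 2 groups, 15 at 0.10, 0 with 1 probe set per gene (limma, 1405 at an unadjusted p under 0.05), 1 with an offset of 1, 7 with an offset of 64 and 0 with the skeletal muscle covariate, 2 spike-in sets or little skeletal muscle. In tibolone against CEE+MPA 1820 became 799 with no filter, 215 with only the 2 groups, 3750 at 0.10, 981 with 1 probe set per gene, 1128 with the luminal covariate, 747 with the skeletal muscle covariate, 735 with 2 spike-in sets and 0 with little skeletal muscle. Leaving out 1 array gave 6 to 26 for CEE against control, 348 to 1981 for CEE+MPA against control, 4 to 10 for tibolone against control, 5 to 13 for CEE+MPA against CEE, 0 to 238 for tibolone against CEE and 209 to 3333 for tibolone against CEE+MPA. The gene values followed were those of called genes and of the fixed panel, whether or not the panel genes had passed. With 1 array left out, 792 of these values stayed on their side of the threshold, 267 lost and 5 gained a call. The 792 include panel genes that did not pass in either fit, so they are not all calls that were kept. Of the list calls 323 stayed and 37 were lost. All 45 list calls were lost with a correlation estimated for each list, and fry lost 30 and kept 15. With the luminal epithelial mean as a covariate 1 list call was lost and 44 stayed. Genes near a signal of 60.2 are limited by signal over background.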

Other observations

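The probe sets in this paragraph were chosen after their values were seen. Some probe sets differed strongly between groups while at least 1 other of the same gene did not. For TMPRSS3, a membrane protease gene, MmugDNA.5037.1.S1_s_at had signals of 25.7 ± 12.1 in controls, 2247 ± 1319 with CEE, 19.4 ± 15.5 with CEE+MPA and 80.7 ± 83.4 with tibolone (SD, n = 4 each), and MmugDNA.19039.1.S1_at 305 ± 84.0, 288 ± 176, 193 ± 194 and 182 ± 74.0. Its other probe sets were MmugDNA.42486.1.S1_at, with 235 ± 49.5, 229 ± 106, 176 ± 150 and 170 ± 49.2, and MmuSTS.1653.1.S1_at, with 71.8 ± 29.6, 102 ± 42.1, 221 ± 138 and 123 ± 54.3. For ERICH3, MmugDNA.10470.1.S1_at had 36.6 ± 12.1, 694 ± 342, 82.9 ± 17.0 and 1185 ± 787, and MmugDNA.37642.1.S1_at 302 ± 85.0, 279 ± 88.7, 288 ± 37.6 and 311 ± 110. The ERICH3 probe set MmugDNA.32943.1.S1_at was also higher with CEE and tibolone, at a lower signal (11.2 ± 7.56, 55.6 ± 22.5, 11.1 ± 9.01 and 58.1 ± 38.3), without passing against control, and MmugDNA.2134.1.S1_at had 104 ± 33.0, 94.2 ± 3.51, 114 ± 33.7 and 107 ± 33.2. For SPATA2, MmuSTS.802.1.S1_at had 45.0 ± 40.6, 742 ± 610, 38.9 ± 27.9 and 1528 ± 454, MmuSTS.2200.1.S1_at 231 ± 18.2, 211 ± 23.3, 191 ± 30.6 and 251 ± 55.7, and MmugDNA.38201.1.S1_at 121 ± 9.06, 119 ± 31.9, 102 ± 8.87 and 135 ± 33.9. Without a symbol, MmuSTS.335.1.S1_at had 71.1 ± 49.5, 858 ± 721, 96.8 ± 32.5 and 1157 ± 462, and MmugDNA.34701.1.S1_at 90.4 ± 27.1, 112 ± 40.0, 125 ± 22.9 and 559 ± 189.

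Fixed lists past the threshold in none of the 6 comparisons are given with their lowest camera adjusted p. These were 0.255 for progestogen response genes, 0.324 for glucocorticoid response genes, 0.215 for androgen response genes, 0.0949 for luminal epithelial markers, 0.0838 for T and NK cell markers and 0.174 for B and plasma cell markers. Skin keratinocyte markers had 0.137, Schwann cell and nerve markers 0.159, EGFR family genes 0.370, unfolded protein and secretory pathway genes 0.174 and cholesterol and fatty acid synthesis genes 0.216. Steroid metabolism genes had 0.196, steroid receptors and their coregulators 0.0786 and apoptosis and survival genes 0.0838. Within a single spike-in set some of them passed. In the low set B and plasma cell and skin keratinocyte markers were lower with CEE than control (0.0341 each), as were skin keratinocyte markers with CEE+MPA (0.0398). In the high set Schwann cell and nerve markers were lower than control with CEE+MPA (0.0352) and tibolone (0.0375), and unfolded protein and secretory pathway genes were higher with CEE+MPA than CEE (0.0377).

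CEE+MPA against control and tibolone against CEE+MPA share the CEE+MPA arrays. Between these comparisons 297 probe sets were higher and then lower and 639 lower and then higher. Sharing the arrays alone makes such opposite calls more frequent.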
